A study of Drosophila melanogaster with 4 samples.

How the data were processed

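Chromatin from third-instar Oregon-R larvae was fixed with formaldehyde, sonicated and immunoprecipitated with an antibody to ubiquitinated histone H2B, per the labels' protocols, and the DNA was sequenced. The labels name 2 immunoprecipitated samples and 2 inputs, each pair numbered as replicates 1 and 2. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are on FlyBase release 5, per the file headers. The program that called the regions, its thresholds, and how the inputs were used are not given in the sources used here. How the combined list was made from the replicates, by pooling reads or by joining lists, is likewise not given. Joining the 2 replicate lists as they stand cannot be the whole of it, because 906 combined regions overlap no region of either.

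The deposited files are lists of enriched regions in GFF3 format, each region with a start, an end and 1 score, as the authors gave it. The unit of the authors' score is not stated. It was continuous, at or below 3.61, and fell below 0 only for 1 region of the combined list that the file itself calls depleted, so it carries a sign as a log ratio would, with no base named. The score was therefore used to describe, rank or filter regions within a list, to correlate matched regions between the replicates and, in the closing observations, to compare scores between X and the autosomes and correlate score with width within each list. The comparison of scores took the median score of the regions in each 1 Mb window and then the mean of these medians over windows. At equal width, each score was first replaced by its residual from a quadratic fit on log10 width. Differences of scores are in the score's own unstated unit. The depleted region was left out of all counts of enriched regions. The narrowest region was 1001 bp in the combined list and 1301 bp in both replicate lists. No list gives read counts, so depth is unknown and no count model applies.

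Samples were grouped by their titles. The 5 major arms (119 Mb), chromosome 4, the 6 heterochromatic sequences and U were handled as named in the files, with lengths from the headers. Uextra (29.0 Mb) held no region in any list. Region widths, covered bases and coverage per sequence were computed with Python 3.11.15 and numpy 2.4.6, with scipy 1.17.1 for ranks and matplotlib 3.10.9 for plots. Overlap between replicates was counted at a minimum of 1 bp and tested one-sided against 1000 circular rotations of replicate 2 within each sequence, which keep widths and spacing. Scores of regions that were each other's best match were compared by Spearman's rho and Pearson's r with 100000 permutations. Coverage on X and the autosome arms was compared in 1 Mb windows with a two-sided permutation test of 100000 resamples, and the interval of the difference came from 10000 bootstrap resamples of windows. All of these tests permute regions or windows and say how firmly placement differs from chance in these lists. They do not measure variation between animals.

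The regions named were chosen by a rule set before the data were examined, as were the alternatives unless stated otherwise. The rule took the 10 highest scores and the 10 widest regions of the combined list that overlap a region in both replicates, and the chromosome arms. The comparisons of chromosome 4 and heterochromatin with arm segments, the split of regions by partner, and the single windows, gaps and other regions named were chosen after their values were seen. Planned tests of gene lists, of position within genes and of exons and introns, with the genes that the rule would have named, were not run. The files name no genes, the gene table at hand is on release 6, and positions were not converted between builds. Regions are therefore given by position alone.

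The tests were tried on simulated data. With the 5036 major-arm regions of replicate 1, 6 of 100 unrelated placements reached a p of 0.05 or less. With 70% of the regions kept in place, 74.0% were found overlapped, the excess being chance overlap of moved regions. Over 119 windows, 10 of 200 draws without a difference reached that level, and 199 of 200 did when 10 percentage points were added to X, with a mean estimate of 10.1 points. These draws shuffled the window values, so they could not test how likeness between neighbouring windows affects the test. Over 4298 simulated pairs with a correlation of 0.9, the estimate was 0.90. Alternatives covered a reciprocal overlap of 50%, the top 50% of scores, random placement, windows of 250 kb, merging of regions under 500 bp apart, and each replicate alone.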

Results

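Chromatin immunoprecipitation followed by sequencing was used to map histone H2B carrying ubiquitin in third-instar larvae of the wild-type Drosophila melanogaster strain Oregon-R. Ubiquitin on histone H2B is known from textbook work as a mark placed over genes while they are transcribed. The antibody was the mouse monoclonal NRO3, raised to the branch point between ubiquitin and human H2B. The series held 2 immunoprecipitated samples (replicates 1 and 2) and 2 input samples of unselected chromatin. The values described here are 3 lists of enriched regions, 1 for each replicate and 1 combined list for the replicate set. The input samples were not analysed here. Read depth was unknown, since the lists hold positions and scores but no read counts, and no counting interval could be given. The labels do not say that the replicates came from separate groups of larvae, so the spread between them may be technical.

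The first question was how much of the larval genome carried the mark and in what kind of region. In the replicates, enriched regions covered 25.1% ± 0.855 (SD, n = 2) of the 5 major chromosome arms (2L, 2R, 3L, 3R and X), or 29.8 Mb ± 1.02 (SD, n = 2). Replicate 1 held 5135 regions and replicate 2 held 5150. The combined list held 5627 enriched regions and covered 29.4% of the major arms. Most regions were a few kilobases wide. The median width was 3.39 kb ± 0.0233 (SD, n = 2) in the replicates and 3.54 kb in the combined list, where the middle 50% of widths lay between 2.00 and 7.07 kb. Broad regions nevertheless held much of the marked sequence. In the combined list, the 890 regions of at least 10 kb made up 15.8% of all regions and held 51.5% of the covered bases. In replicates 1 and 2, regions of at least 10 kb held 44.7% and 47.4% of the covered bases. Regions of at least 50 kb numbered 34 in the combined list, 23 in replicate 1 and 25 in replicate 2.

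The second question was whether the 2 replicates marked the same places. Their regions coincided far more than regions placed elsewhere on the same arms. The bases covered in both replicates were 85.0% of the bases covered in either (Jaccard index). Of the regions of replicate 1, 4788 of 5135 (93.2%) overlapped a region of replicate 2 by at least 1 bp. In the other direction, 4540 of 5150 (88.2%) overlapped. When replicate 2 was rotated along each sequence 1000 times, the Jaccard index averaged 14.3% and never passed 21.5%. The one-sided permutation p was 0.001 for each of these measures, the smallest that 1000 rotations can give, and 0.0012 after Benjamini-Hochberg adjustment over 6 tests. Requiring that the overlap span at least 50% of both regions lowered the shared share to 77.6% of replicate 1, against a mean of 6.94% under rotation.

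The overlap was similar on the 5 major arms and lower on 4 of the 5 heterochromatic sequences that held regions in both replicates. The Jaccard index was 85.8% on 2L, 84.1% on 2R, 85.7% on 3L, 86.7% on 3R and 83.5% on X. It was 78.7% on chromosome 4, the small autosome. On 2RHet, 3LHet and 3RHet, sequences assembled from heterochromatin, it was 52.5%, 54.7% and 52.9%, with 8 to 21 regions per replicate on each. On XHet, with 4 and 2 regions, it was 53.6%, while on 2LHet, with 5 and 4 regions, it was 86.6%, level with 3R. These differences between sequences were not tested.

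Regions found in 1 replicate were narrow. The 347 regions of replicate 1 without a partner had a median width of 1.60 kb, against 3.62 kb for those with one, and held 2.00% of that list's bases. The 610 unpartnered regions of replicate 2 had a median width of 1.73 kb, against 3.87 kb, and held 3.82% of the bases. A wide region meets the 1 bp rule by chance more readily than a narrow one, so part of this difference may come from the rule. Widths were not compared with those under rotation. The lists were not identical, but this does not show that the replicates were independent.

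The authors' score ranked shared regions alike in both replicates. Over the 4298 pairs of regions that were each other's best match, Spearman's rho was 0.924 and Pearson's r was 0.947, each with a permutation p of 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 3e-05. Without the 2 pairs farthest from the median of replicate 1, r was 0.947. These are correlations across regions, which are not independent replicates. Rank agreement was lower among narrow regions, with rho of 0.603 in the narrowest width quartile of replicate 1 and 0.929 in the widest. The spread of scores within each quartile was not compared, and a smaller spread lowers rho. A larger error in narrow regions can therefore not be read from these values.

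**Figure D1:**
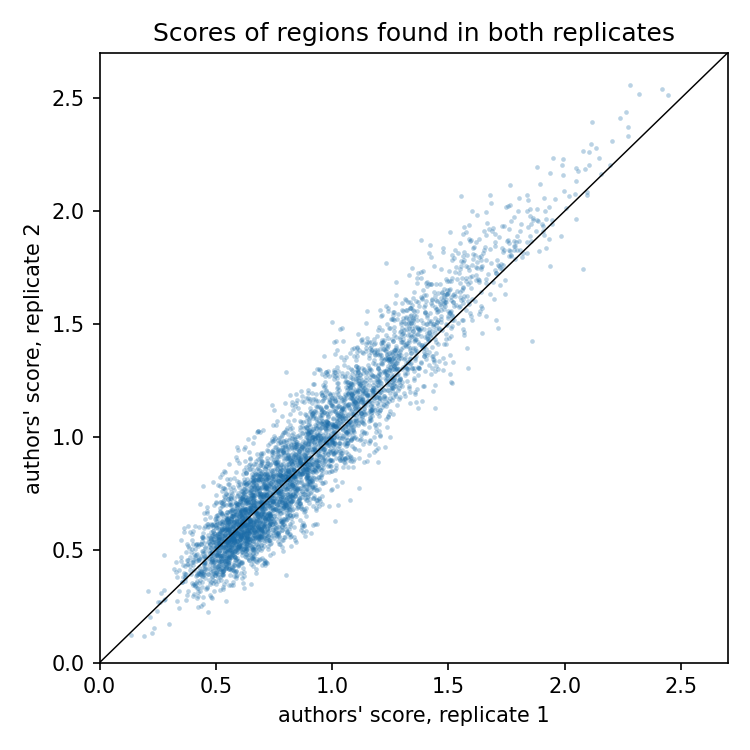
Authors' score (no unit given) in replicate 1 on the x axis and replicate 2 on the y axis, 1 point for each of 4298 pairs of best-matching regions, with the line of equality. The points scatter around the line, with a Spearman's rho of 0.924, and the highest lie mostly above it, replicate 2 having the higher score in 10 of the 10 highest-scoring regions named in the text.

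The third question was how the mark was spread over the chromosomes. All 5 major arms were covered to a comparable degree, chromosome 4 less, and heterochromatic sequences very little. Mean coverage in the replicates ranged from 22.2% ± 0.698 (SD, n = 2) on 2L to 28.0% ± 1.15 (SD, n = 2) on 2R. Coverage on 3L was 24.8% ± 0.814, on 3R 25.3% ± 0.651 and on X 25.1% ± 1.04 (SD, n = 2 each). Chromosome 4 was covered at 14.5% ± 1.02 (SD, n = 2). It held 39.2 regions per Mb ± 3.14 (SD, n = 2), within the span of the major arms (36.8 on 2L to 50.8 on 2R), but its regions had a smaller median width. Their median width was 2.90 kb in replicate 1 and 2.87 kb in replicate 2, against at least 3.16 and 3.26 kb on each major arm. Chromosome 4 was not outside the range of the major arms at its own scale, because 11.0% of the arm segments of equal length were covered no more than it was in the combined list (9.12% and 10.2% in replicates 1 and 2). The segments started every 10 kb and overlapped, so these are not shares of separate segments. They also took in the centromere ends of the arms, where coverage fell on 2L, 2R, 3L and X.

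**Figure D2:**
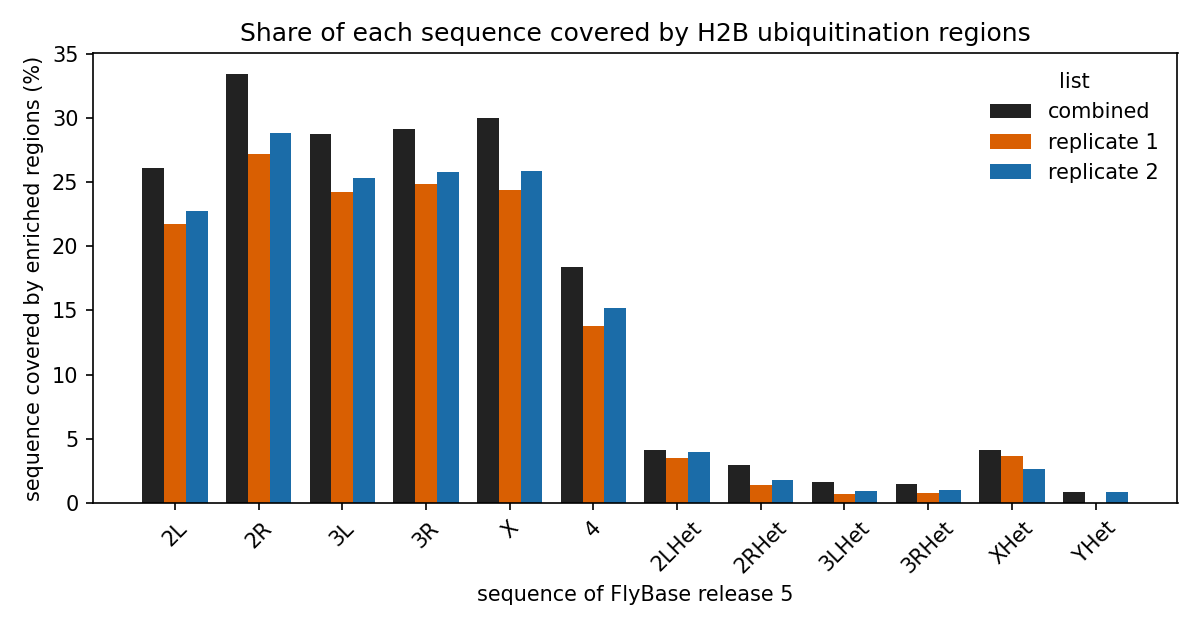
Share of each sequence covered by enriched regions in percent (y axis, from 0) for the major arms, chromosome 4 and the heterochromatic sequences (x axis), with 1 bar for each list. The 5 major arms lie between 21.7% and 33.4%, chromosome 4 between 13.8% and 18.4%, and no heterochromatic sequence is above 4.12%.

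The 6 heterochromatic sequences, 9.28 Mb together, were covered at 1.26% ± 0.218 (SD, n = 2) in the replicates and 2.20% in the combined list, against 29.2% for the 4 autosome arms in the combined list. On 2RHet, the longest at 3.29 Mb, coverage was 2.99% in the combined list. The least covered of 10261 overlapping major-arm segments of that length was at 12.9%. On 3LHet and 3RHet it was 1.65% and 1.47%, and no arm segment of equal length was covered as little in any of the 3 lists. For the 3 short heterochromatic sequences this comparison could not decide. The least covered arm segment of their length was at 0%, so even a coverage of 0% would have lain within the range. In the combined list 2.66% of arm segments were covered no more than 2LHet, 7.24% no more than XHet and 0.852% no more than YHet. On YHet, 1 region was called at 304738 to 307683 in replicate 2 and at 304736 to 307664 in the combined list, and none in replicate 1. The unplaced sequence U was covered at 0.167% ± 0.0471 (SD, n = 2). Repeats and assembly gaps, where reads cannot be placed, were not measured, so a low share on these sequences cannot be separated from unreadable sequence.

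X and the autosome arms did not differ in covered share by more than the spread between windows. In 1 Mb windows of the combined list, coverage was 30.5% ± 8.98 (SD, 22 windows) on X and 29.2% ± 9.91 (SD, 97 windows) on the autosome arms. The difference, X minus autosomes, was 1.29 percentage points, with a 95% bootstrap interval over windows from -2.99 to 5.33. The two-sided permutation p over windows was 0.573, and 0.573 after adjustment over 6 tests. The difference was 0.408 points in replicate 1 and 0.729 points in replicate 2, and in the combined list 0.334 points without arm 2L and 2.52 points without arm 2R. Windows along an arm are neighbours and are not independent samples.

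Coverage varied widely along the arms, and both replicates followed the same course. The most covered window of the combined list was 5 to 6 Mb on 3R at 50.1% (42.2% in replicate 1 and 43.1% in replicate 2). The window from 17 to 18 Mb on 2R was covered at 48.3%, and that from 3 to 4 Mb on 3L at 46.7%. The least covered were the last 2 windows of 3L, at 3.13% and 2.82%, and the window from 15 to 16 Mb on 2L at 6.90%. Across the 119 windows, which are not independent, Pearson's r between the replicates was 0.994. Replicate 2 was the more covered in 110 of 119 windows, by 1.21 percentage points ± 0.943 on average (SD over windows).

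**Figure D3:**
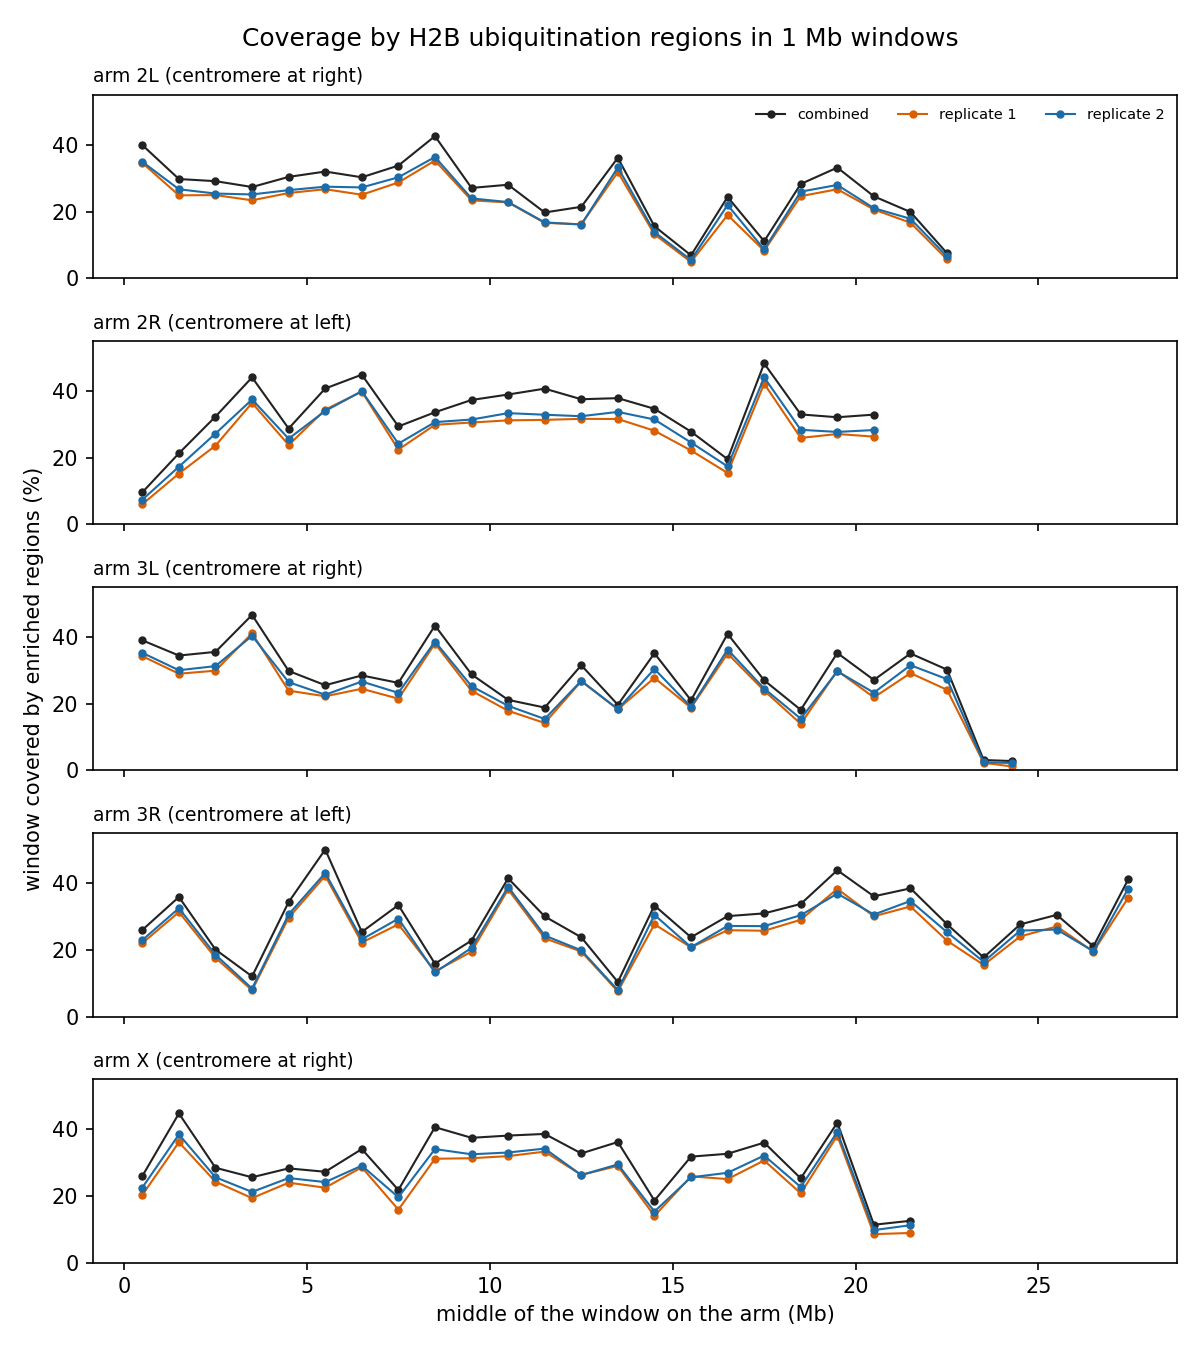
Percent of each 1 Mb window covered by enriched regions (y axis) against the middle of the window in Mb (x axis) on the 5 major arms, with 1 line for each list. The lines of the replicates run together, and coverage falls to 2.82% at the centromere end of 3L and peaks at 50.1% on 3R.

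The regions with the highest scores lay on 3L, 2R and 3R. Among regions of the combined list seen in both replicates, 5 of the 10 highest scores were on 3L, 3 on 2R and 2 on 3R. The highest was 2.49, at 16132500 to 16158110 on 3L (FlyBase release 5), a region of 25.6 kb that scored 2.42 in replicate 1 and 2.54 in replicate 2. The others on 3L were at 15228148 to 15237684 (score 2.45), 3400478 to 3418292 (2.35), 8426194 to 8436250 (2.26) and 17544918 to 17551412 (2.20). Those on 2R were at 15998374 to 16005756 (2.37), 1988350 to 2020142 (2.33) and 17104014 to 17138194 (2.30). Those on 3R were at 23389910 to 23411824 (2.30) and 27721408 to 27763730 (2.28). These 10 regions were 6.50 to 42.3 kb wide, each was a single region in both replicates, and either replicate covered at least 91.7% of each.

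The widest regions were a different set, spread over all 5 major arms. None of the 10 widest was among the 10 highest scores, and their scores ran from 1.04 to 2.03. The widest 2 were 114 kb each, at 9276334 to 9390258 on X (score 1.04) and 22287804 to 22401488 on 3L (1.68). On 2R, broad regions lay at 17281082 to 17384366 (103 kb, score 2.03), 13152712 to 13240758 (88.0 kb) and 6911580 to 6994664 (83.1 kb). X held further ones at 12097532 to 12188128 (90.6 kb) and 19247094 to 19332372 (85.3 kb). On 3R they lay at 4896062 to 4984038 (88.0 kb) and 21341956 to 21426930 (85.0 kb), and on 2L at 7891952 to 7977656 (85.7 kb). The bases of these 10 regions were covered to at least 89.6% in replicate 1 and 96.7% in replicate 2, yet only 2 of the 10, those from 7891952 on 2L and from 19247094 on X, were 1 unbroken region in both. The region on X from 9276334 was called as 8 regions in replicate 1 and 3 in replicate 2.

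**Figure D4:**
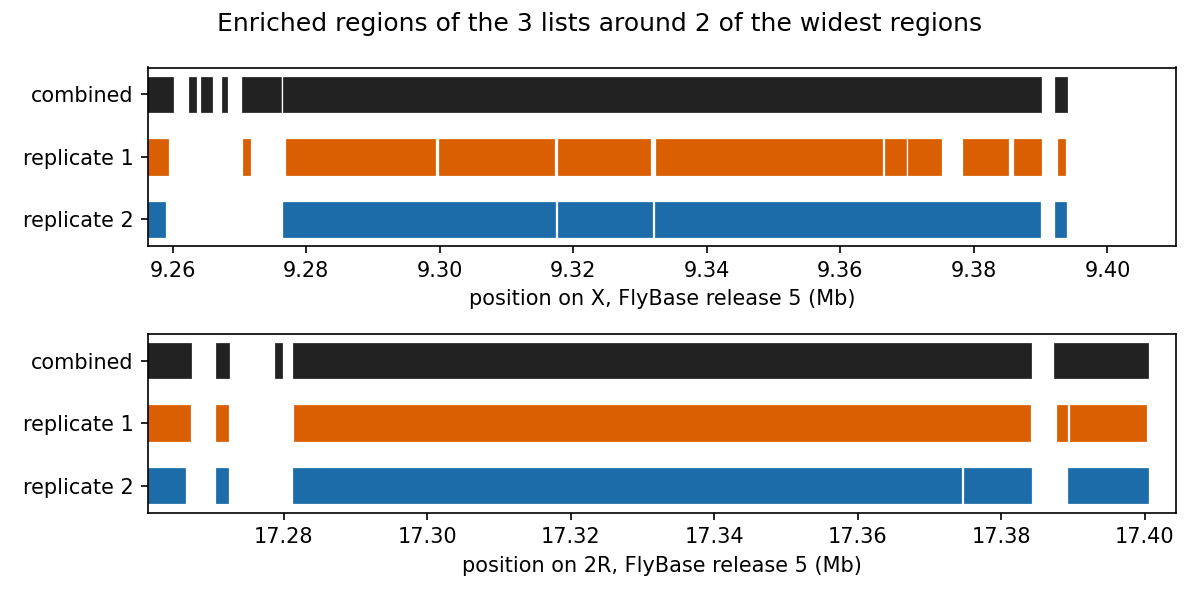
Enriched regions (bars, drawn to scale) of the combined list and both replicates around the 114 kb region on X (top) and the 103 kb region on 2R (bottom), against position in Mb. The region on X is 1 bar in the combined list, 8 in replicate 1 and 3 in replicate 2.

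The combined list held most of what the replicates held and added narrow regions. Of its 5627 regions, 3940 overlapped a region in both replicates, and these held 91.3% of its bases. A further 285 overlapped replicate 1 alone and 496 replicate 2 alone, while 906 (16.1%) overlapped neither. Those 906 had a median width of 1.32 kb and held 3.67% of the bases. In total 2.99 Mb of the combined list (8.42%) lay outside both replicates. All 2065 of its regions of 5 kb or more overlapped a region of at least 1 replicate. Here too a wide region overlaps by chance more readily than a narrow one.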

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

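The alternatives that left out single arms or sequence near centromeres, rotated the X label, used scores by window or left out the narrowest regions were chosen after the data were seen. Overlap between replicates and score agreement kept their direction and stayed past the threshold under all alternatives that were run, with the Jaccard index between 82.6% and 85.2% and Spearman's rho between 0.603 and 0.932. The difference in covered share, X minus autosomes, stayed above 0 and short of the threshold under every alternative run. It was 0.408 points without replicate 2 and 0.729 without replicate 1, and 0.334 points without arm 2L and 2.52 without 2R. Keeping the top 50% of scores left 2814 regions in the combined list, 2568 in replicate 1 and 2575 in replicate 2, which by construction is about 1 in 2, and these covered 23.6%, 19.1% and 20.2% of the major arms. Merging regions under 500 bp apart left 4475 regions in the combined list. No region was under 500 bp wide, so that filter moved nothing. The score difference between X and autosomes was 0.0619 in the combined list, 0.0771 without replicate 2 and 0.0978 without replicate 1. In the combined list its p rose from 0.0086 to 0.227 when the X label was rotated along the joined arms in place of free permutation of windows, and the cause was not tested. No paired analysis was possible because the input samples have no region list here, so immunoprecipitated and input samples of the same number could not be compared. Alternatives for the gene, position and exon results were not run, nor was coverage of gene bases on X, because no annotation on release 5 was at hand. Read depth is unknown and limits every list, and whether a region missing from 1 replicate was missed for lack of reads could not be tested.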

Other observations

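The tests in this part on width and score, on scores of X and on narrow regions were chosen after the values were seen, and those on centromere ends, long gaps, added bases and copies of X were set down beforehand. Wide regions had higher scores than narrow ones. In the combined list the median score was 1.31 for the 282 regions of at least 20 kb and 0.356 for the 1420 under 2 kb. Spearman's rho between width and score was 0.807 in the combined list, 0.822 in replicate 1 and 0.826 in replicate 2, each with a permutation p of 1e-05, the smallest possible, and an adjusted p of 2.6e-05 over 13 tests. Without the 2 widths farthest from the median, Pearson's r with log10 width stayed at 0.731 in the combined list. These are correlations across regions, which are not independent. How the score was computed is not given, so a link built in by the way regions were called or scored cannot be told apart.

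Long stretches of the major arms held no called region, and unreadable sequence within them was not measured. Gaps of at least 100 kb between neighbouring regions numbered 197 in the combined list and added up to 34.0 Mb, 219 in replicate 1 and 214 in replicate 2. In 1000 random placements of the combined list's regions such gaps averaged 9.89 and never passed 21. Random placement of the called regions, each on its own over the whole arm, is therefore excluded. Placement on readable sequence alone, or of neighbouring regions as 1 unit, was not tested. The longest were 478 kb at 15768173 to 16246095 and 454 kb at 16917025 to 17370653, both on 2L, and 433 kb at 18178831 to 18612323 on 3L. Of the 10 longest, 9 held no region of either replicate, and the exception, at 13509515 to 13900253 on 3L, held 1 region of replicate 1. Per Mb, 2R held the fewest such gaps (1.28) and 2L the most (1.91).

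Coverage fell near most centromeres. The 2 windows of each arm next to the centromere were covered at 15.0% ± 10.6 (SD, 10 windows) and the others at 30.7% ± 8.54 (SD, 109 windows) in the combined list, a difference of -15.7 percentage points (two-sided permutation p 1e-05, the smallest possible, adjusted 2.6e-05), and of -13.8 in each replicate. Taking all 11 windows within 2 Mb, a choice not set down beforehand, gave -14.3. The windows at an arm end are neighbours and not independent, and free permutation ignores this, so the p may be too small. No rotation of labels was run here. The difference was -13.5 points on 2L, -20.0 on 2R, -27.4 on 3L and -20.4 on X, but 3R went the other way, at 30.9% near the centromere and 29.1% elsewhere. Repeats to which reads cannot be assigned may give such a fall and stay open beside a lower level of the mark, as no genome sequence was used here.

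Regions on X had higher scores than those on the autosomes in both replicates. The median score was taken in each 1 Mb window, and the mean of these medians differed, X minus autosomes, by 0.0619 in the combined list, 0.0771 in replicate 1 and 0.0978 in replicate 2. When the X label was rotated along the arms, p was 0.227, 0.0420 and 0.0084 (adjusted over 13 tests 0.227, 0.0455 and 0.0112). The combined list therefore did not pass in this test, and 0.0084 is the smallest that 119 rotations can give. Neighbouring rotations share most of their windows, so the 119 are not independent and these p-values may be too small. X is also 1 chromosome, so a trait of X cannot be separated from variation between chromosomes. Wider regions on X are argued against. Regions on X had a median width of 3.41 kb in replicate 1 and 3.46 kb in replicate 2. These lay below 3L (3.44 and 3.61 kb) and above 2R (3.16 and 3.26 kb). The score difference at equal width was 0.0796 in replicate 1 and 0.0893 in replicate 2 (rotation p 0.0084 in each, adjusted 0.0112). It was 0.0613 in the combined list (rotation p 0.0168, adjusted 0.0199). How the authors normalised to input and the sex of the larvae remain open, and no biological explanation was tested. A loss of weak regions on X had no sign in region counts. In the replicates X held 44.5 regions per Mb on average, above 2L (36.8), 3L (39.5) and 3R (41.0) but below 2R (50.8). In the combined list X held 49.5 per Mb against 45.1 on the autosomes, but the interval of the difference, -1.93 to 10.5, spans 0. These counts therefore do not decide on such a loss.

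If the larvae were of both sexes, fewer copies of X than of autosomes, left uncorrected, stay open as an influence on X. A covered share or a median score of X at or above the autosomes was set down beforehand as evidence against them. The covered share met this bound, with X above the autosomes by 1.29 points. Its interval, from -2.99 to 5.33, also holds values below 0, so the covered share was not taken to decide. That use of the interval was not part of the bound set down beforehand. The bound on the score was met too, with X above the autosomes in all 3 lists. It was judged a wrong choice afterwards, because only called regions have scores and losing weak regions can raise their median. Region counts showed no such loss on X, at 49.5 per Mb against 45.1 on the autosomes in the combined list. The interval of that difference, -1.93 to 10.5, spans 0. The replicate lists, with fewer regions than the combined list, had median scores of 0.775 and 0.765 against 0.593. This contrast does not show that effect alone, because scores may differ between lists. Regions in replicate 1 alone had a median of 0.549, and combined regions overlapping replicate 1 alone had 0.366. For replicate 2 these were 0.556 and 0.402.

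The combined list reached beyond both replicates, and its 3 highest scores lay there. These were 3.22 at 12393414 to 12394414 on X, 3.03 at 8695168 to 8696168 on U and 2.92 at 311282 to 312312 on 2R, regions of 1001, 1001 and 1031 bp that neither replicate held. All 3 were narrower than the narrowest replicate region (1301 bp), so a difference in minimum width may explain their absence from the replicates, and only 9.32% of the 472 combined regions under that width overlapped a replicate region. That limit is not the whole cause for the 906 regions found in neither replicate, of which 47.2% (exact 95% binomial interval 43.9 to 50.6) were that narrow. Of the added bases, 56.4% extended regions seen in a replicate or closed gaps between them and 43.6% lay in regions that overlap neither, so new regions were the smaller part and neither source gave all of it.

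In replicate 1 the highest score, 3.61, belonged to a region of 1.41 kb at 226511 to 227918 on 2RHet that replicate 2 did not hold. The 1 region that the combined list calls depleted, at 17467738 to 17469300 on 3L with a score of -0.00675, overlapped a region that replicate 2 calls enriched, at 17467676 to 17469262 with a score of 0.136.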
